A study of Mikania micrantha with 15 samples.

How the data were processed

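Small RNA libraries were made from flower, leaf, shoot apex, stem and root of Mikania micrantha, 3 per tissue. Per the labels, cuttings were rooted and grown in nutrient solution for 60 days, with 16 h of light and 8 h of dark at 24 °C. RNA was extracted with TRIzol, and libraries were built with a small RNA kit from NEB. The authors deposited, for each library, the distinct sequences with their read counts, which are raw whole numbers without normalization. Adapter trimming, length limits and quality filters were not given in the sources used here. The files held sequences of 18 to 66 nt, and 0.0323% to 0.0354% of reads had a letter other than A, C, G or T. No genome was used.

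Reads of 18 to 30 nt were the total for shares. All deposited reads (16300647 to 26366109 per library) were the total for RPM, the reads per 1000000 deposited reads. A read of 20 to 22 nt was assigned to a family when it matched bases 2 to 19 of a listed sequence (an 18-base core) with at most 1 substitution and a start shifted by at most 1 base. Ties between families were left out. The list of 31 families (65 sequences), 4 control families and 8 passenger (star) strands was written from general knowledge and not taken from a database, as were 14 rRNA, snRNA and tRNA sequences of nucleus or plastid. Structural RNA reads were identical to a stretch of these 14, which leave out the large rRNAs of the nuclear genome. Reads are not independent molecules, so the limit for a count of 0 (3 reads) covers counting error only.

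Families with at least 10 reads in 3 libraries, and sequences of 20 to 24 nt with at least 50 reads in 3 libraries, were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test was used with TMM factors over the families or the sequences, all 15 libraries in 1 model, and Benjamini-Hochberg adjustment at 0.05. Each tissue was set against the mean of the log2 values of the other 4, and each pair of tissues was compared. SE is the log2 fold change over the square root of F. The 7 lists of families were tested with fry of limma 3.58.1, which asks whether a list's families move, on balance, in 1 direction, adjusted over lists and tissues. Its mixed test, which asks for changes in either direction, was run too. Shares were tested with exact permutation tests of the between-tissue F statistic over 1401400 partitions (smallest p 7.1e-07). Each tissue was set against the other 12 libraries over 455 splits, two-sided, adjusted over 50 tests (smallest p 0.0022). Distinct sequences at equal depth are the expected number in a subsample of 10775868 reads. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

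The families named are those of the lists, the 10 largest rises and 10 largest falls past the threshold per tissue, the 3 largest each way per pair of tissues, and the controls. The sequences named are, per tissue, the 2 with the largest rise and the 2 with the most RPM among those higher there. These rules, the lists, the tests and the first set of alternatives were fixed before the data were examined. The alternatives were total reads in place of TMM, DESeq2 size factors, the DESeq2 1.42.0 test, other count minimums, exact matching, up to 2 substitutions, and reads of 19 to 24 nt. For shares they were other totals, distinct sequences, a lower depth, and leaving out structural RNA or the 100 most abundant sequences. The replicate number as a block and leaving out each library were tried for all. After the data were seen, 2 more were added: merging root libraries 2 and 3 and stem libraries 1 and 2, and reducing root to library 1. In the latter root has 1 library, so the spread comes from the other tissues alone, and its values and counts of calls show the size of a change and not its spread within root.

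The tests were checked on simulated counts for leaf against the other tissues. Over 22013 sequences, 23 of 100 changes of 1 log2 unit and 91 of 100 of 2 log2 units were called, with 8 false calls among 21813 unchanged sequences. Over 20 simulated sets of 24 families, 39 of 60 changes of 1 log2 unit and 58 of 60 of 2 log2 units were called, with 5 false calls among 360. In these simulations only leaf was changed, both up and down, and most features were left unchanged. They therefore do not show how the tests behave where most families differ and the scaling shifts. The permutation test called 2 of 40 simulated data sets with no difference and 20 of 20 with 1 tissue shifted by 6 SD, which is too large a shift to gauge small differences.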

Results

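Small RNA was sequenced from 5 tissues of Mikania micrantha, a climbing vine of the daisy family known as an invasive weed. Flower, leaf, shoot apex, stem and root each had 3 libraries, 15 in all. The study's title places them in the regulation of rapid growth, so the tissues were compared for the lengths of their small RNA, for conserved microRNA (miRNA) families and for single sequences. The libraries held from 16300647 reads (root 2) to 26366109 reads (leaf 2). Nothing in the labels says whether the replicates are separate plants, so every p-value measures only the spread between these libraries. Root libraries 2 and 3 differed by no more than sampling noise over the conserved families (chi-square 29.96, 23 degrees of freedom, p = 0.151), while root 1 and 2 had a chi-square of 2032.54. Over single sequences the chi-square per degree of freedom was 1.43 for root 2 and 3 and 1.70 for stem 1 and 2. The 13 other pairs within a tissue had 3.51 to 57.5. These values cover counting error only, and whether the close libraries are separate samples stays open. The libraries were counted as 3 per tissue, as labelled, and calls named below that were lost with the close libraries merged are given with their merged values.

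The shoot apex had the highest mean share of 24-nt small RNA, the length class known for silencing repeats, and root had the lowest. Reads of 24 nt made up 42.5% ± 4.64 (SD, n = 3) of the 18 to 30 nt reads in the shoot apex and 37.3% ± 2.00 in stem. Leaf had 30.8% ± 0.0757, flower 29.6% ± 1.74 and root 14.1% ± 5.86. The tissues differed (exact permutation test, p = 1.2e-05). Root lay below the other 12 libraries in 3 of 3 libraries (exact permutation p = 0.0022, the smallest the design allows, adjusted p = 0.0183). The shoot apex did not pass the correction (exact permutation p = 0.022, adjusted p = 0.0785). Root library 1 held 20.9% of 24-nt reads, against 10.7% in root 2 and in root 3. Signs of RNA quality differed in root, but did not move together between its libraries. Root had 35.8% of reads over 30 nt against 12.9% to 16.4% in the other tissues, with 36.8%, 33.9% and 36.8% in root 1, 2 and 3. There were more 20-nt forms of family reads in root 2 and 3 (medians of 22.7% and 20.8%) than in root 1 (8.59%). That value of root 1 lay within the range of the libraries of the other tissues (5.69% to 9.38%). The log2 ratio of 24-nt to 21-nt reads was 2.54 ± 0.158 in the shoot apex and 0.88 ± 0.421 in root (SD, n = 3), and both means differed from that of the other 12 libraries (exact permutation, adjusted p = 0.03 and 0.0275). Root library 1 (1.37) lay above leaf library 1 (1.31), so only root 2 (0.62) and root 3 (0.66) were below all others. The ratio averaged 1.90 in flower, 1.82 in stem and 1.41 in leaf.

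**Figure D1:**
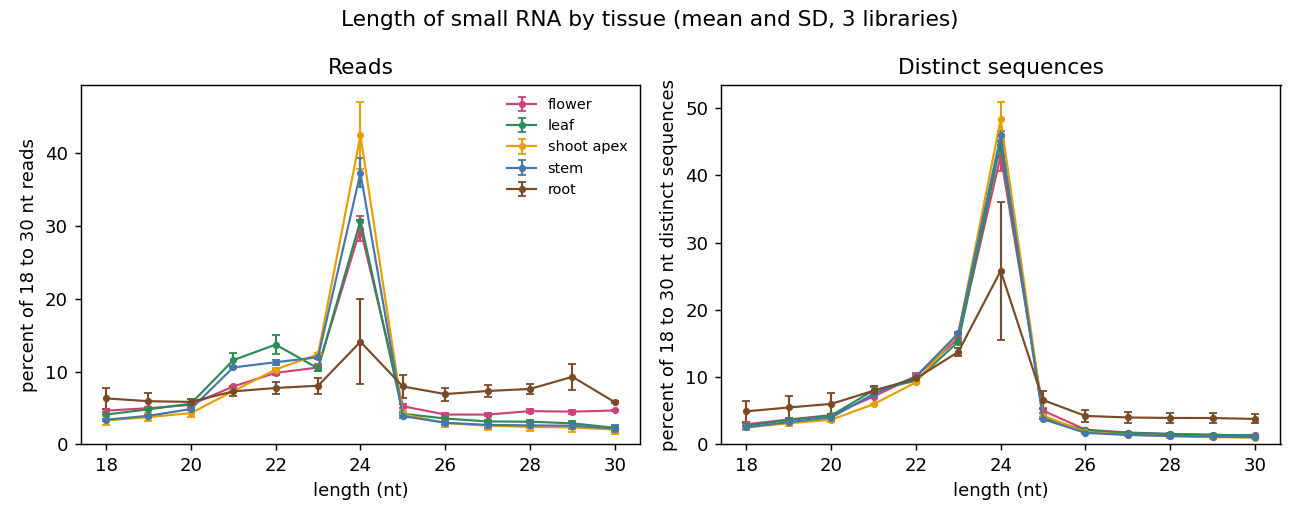
Percent of 18 to 30 nt reads (left) and of distinct sequences (right) at each length in nt, with 1 line per tissue; points and bars are the mean and SD of 3 libraries. The 24-nt peak of reads is highest in the shoot apex (42.5%) and lowest in root (14.1%).

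Leaf had the highest shares of 21-nt and 22-nt reads, the lengths of most miRNA. At 22 nt, 2 abundant sequences that were higher in leaf matched no listed miRNA family. At 21 nt leaf had 11.6% ± 0.942 (SD, n = 3) against a mean of 8.27% in the other 12 libraries, above all of them in 2 of 3 libraries (exact permutation, adjusted p = 0.03). At 22 nt it had 13.7% ± 1.29 against 9.77%, above all of them in 3 of 3 (exact permutation, adjusted p = 0.0183). Root had the lowest means, 7.27% ± 0.700 at 21 nt (exact permutation, adjusted p = 0.188) and 7.74% ± 0.872 at 22 nt (adjusted p = 0.03). These differences depend on the total: with 20 to 24 nt reads as the total, leaf minus root at 21 nt was -1.08 percentage points in place of 4.29, and at 22 nt 0.829 in place of 5.96. Without the 100 most abundant sequences the 22-nt difference was 1.39 points, and with distinct sequences in place of reads it was -0.33. The 2 abundant 22-nt sequences had means of 29468 and 5630 RPM in leaf, against 3043 and 494 RPM in the other 12 libraries. The high 22-nt share of leaf therefore cannot be read as a high share of miRNA. The share without these 2 sequences alone was not tested. The 21-nt difference was 0.0591 points with distinct sequences.

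A was the first base of 80.8% ± 1.56 of 24-nt reads in the shoot apex and of 51.6% ± 14.4 in root (SD, n = 3). Root was below the other 12 libraries in 3 of 3 (exact permutation, adjusted p = 0.0183), with 68.2% in root 1, 43.2% in root 2 and 43.5% in root 3. The difference between shoot apex and root was 29.2 points, 12.6 points with root library 1 alone and 9.79 points over distinct sequences. U was the first base of 41.9% ± 3.41 of 21-nt reads in leaf (exact permutation, adjusted p = 0.0275) and of 29.0% ± 1.85 in root (adjusted p = 0.0641; SD, n = 3). That difference was 12.9 points, 8.53 without the 100 most abundant sequences and 2.32 over distinct sequences.

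Conserved miRNA families took 1.85% ± 0.113 of the reads in stem and 1.85% ± 0.477 in leaf, but 0.616% ± 0.0553 in flower, 0.518% ± 0.0661 in shoot apex and 0.217% ± 0.160 in root (SD, n = 3). The tissues differed (exact permutation p = 0.00043), while no single tissue passed the correction against the other 12 libraries (adjusted p from 0.0785 to 0.534). The difference between stem and root was 1.63 points, 0.667 without the 100 most abundant sequences and -0.0016 over distinct sequences. At an equal depth of 10775868 reads, 5681695 ± 416336 distinct sequences were expected in the shoot apex and 2325406 ± 693195 in root (SD, n = 3; exact permutation p = 1.3e-05 between tissues). Fragments of listed nuclear structural RNA were highest in flower at 1.99% ± 0.181 (exact permutation, adjusted p = 0.0183) and stood at 1.27% ± 0.281 in root. The flower share was mostly 5S rRNA (1.61% ± 0.186), and without 5S rRNA root had the highest mean (0.900% ± 0.252), against 0.380% ± 0.0136 in flower (SD, n = 3; not tested). Flower minus shoot apex was 1.38 points, 0.895 with 20 to 24 nt reads as the total, 0.817 without the 100 most abundant sequences and 0.0115 over distinct sequences. Plastid RNA fragments, a check on green tissue, made up 0.387% ± 0.0204 in leaf and 0.0651% in the other 12 libraries (SD, n = 3; exact permutation, adjusted p = 0.0183). Leaf minus flower was 0.338 points, 0.118 with 20 to 24 nt reads as the total and 0.0063 over distinct sequences.

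Of 31 listed conserved families, 24 had enough reads to test, and 18 of them differed between the tissues (edgeR, adjusted p under 0.05). By reads per 1000000 deposited reads (RPM), the largest were miR396, known to act on growth-regulating factors, with 7303 ± 2614 in leaf, and miR166, known to act on HD-ZIP III factors, with 3696 ± 847 in leaf (SD, n = 3). miR319, known to act on TCP factors, had 2454 ± 169 in stem. No reads were assigned to miR482, miR535 or miR828, which allows up to 0.184 RPM in the smallest library. miR162 had 16 reads over all libraries, miR397 64, miR827 1 and miR2111 35, too few to test. Families known mainly from Arabidopsis and its relatives served as background: miR158 had 1 to 15 reads per library, miR161 up to 3, miR163 up to 2 and miR173 0. Fold changes below compare a tissue with the mean of the log2 values of the other 4, scaled by factors from the families themselves. Total reads in place of these factors shifted the median family by -0.58 in flower, 0.84 in leaf, 0.31 in shoot apex, 0.67 in stem and -1.27 in root (log2). Each change is therefore relative to the other families, and 28 of the 120 family and tissue values change sign under total reads.

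**Figure D2:**
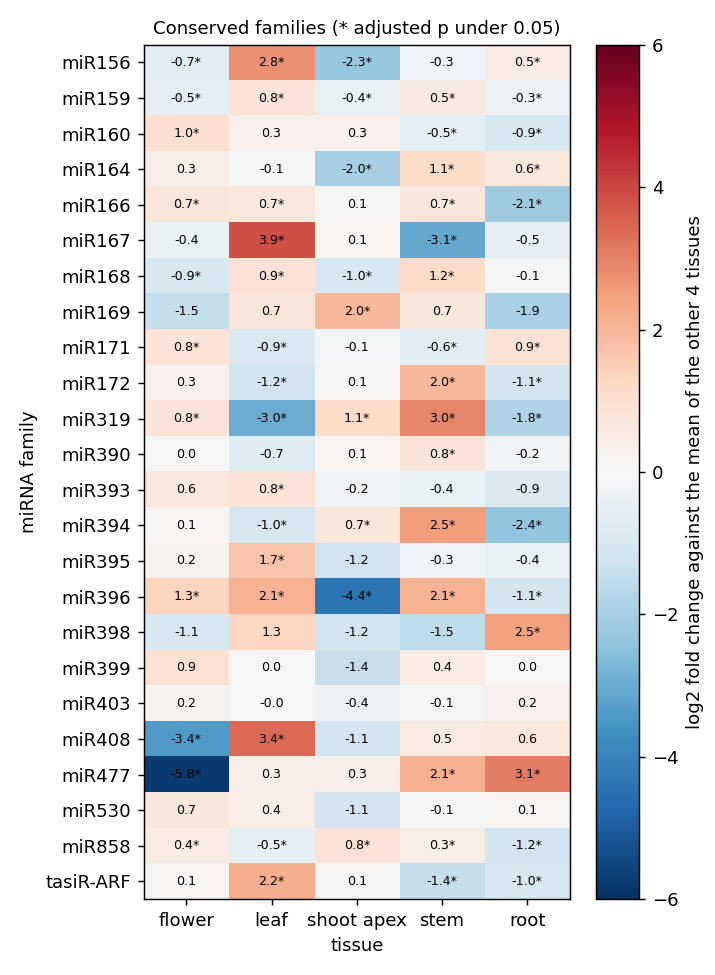
Log2 fold change of 24 families (rows) in each tissue (columns) against the mean of the other 4 tissues, with scaling by the families; asterisks mark an edgeR adjusted p under 0.05. The lowest values are miR477 in flower (-5.76) and miR396 in shoot apex (-4.39), the highest is miR167 in leaf (3.85), and these 3 keep their sign under total reads while 28 of the 120 values do not.

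Leaf was marked by high miR167, miR156, miR408 and miR396 and by low miR319, all called under both scalings. miR167, known to act on auxin response factors, had 1453 ± 274 RPM (SD, n = 3) and was 14.5-fold above the mean of the other tissues (log2 3.85 ± 0.25 SE, edgeR adjusted p = 7.59e-09). miR156, known to repress SPL factors and keep the juvenile phase, had 207 ± 25.1 RPM (log2 2.75 ± 0.14 SE, adjusted p = 1.89e-09). miR408, known to act on copper proteins, had 92.1 ± 64.6 RPM (log2 3.42 ± 0.65 SE, adjusted p = 0.000455). tasiR-ARF, the trans-acting small RNA against auxin response factors, had 8.47 ± 3.32 RPM (log2 2.18 ± 0.24 SE). miR396 was 4.19-fold higher and miR319 7.93-fold lower (adjusted p = 2.65e-09 and 1.31e-08). Leaf minus stem was log2 -0.02 for miR396 (edgeR adjusted p = 0.927), so this family does not set leaf apart from stem. miR408 was not called between leaf and stem (log2 2.33, edgeR adjusted p = 0.0607) or leaf and root (2.22, adjusted p = 0.0674). Leaf library 2 had 22.9 RPM of miR408, below the 32.6 RPM of stem library 3. miR172, known to act on AP2-type factors, fell (log2 -1.21 ± 0.23 SE, adjusted p = 0.000448), but by total reads it was -0.43 (adjusted p = 0.292). By the families' factors 10 families were higher and 5 lower (66.67% higher), and by total reads 17 and 1 (94.44%). The rise of miR395 (log2 1.71), known to act on sulfate assimilation, rested on leaf library 2 (0.31 without it, adjusted p = 0.658). The falls of miR394 (-0.99) and miR171 (-0.94) were -0.21 and -0.08 by total reads and no longer called, and miR858 turned from -0.48 to 0.40.

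Stem stood out by miR319, miR394 and miR172, and miR477 and miR396 also lay above the mean of the other tissues. All were called higher under both scalings. miR396 did not set stem apart from leaf (leaf minus stem log2 -0.02, edgeR adjusted p = 0.927). Nor did miR477 set it apart from root (stem minus root log2 -0.75, edgeR adjusted p = 0.0646). miR319 was 7.73-fold above the mean of the other tissues (log2 2.95 ± 0.14 SE, edgeR adjusted p = 7.32e-10). miR394, known to act on an F-box gene of the shoot meristem, had 1134 ± 171 RPM (SD, n = 3; log2 2.53 ± 0.22 SE, adjusted p = 3.76e-07). miR172 had 48.2 ± 7.97 RPM (log2 1.95 ± 0.19 SE) and miR477 111 ± 37.0 RPM (log2 2.12 ± 0.23 SE). miR168, known to act on ARGONAUTE1, had 121 ± 28.1 RPM (log2 1.16 ± 0.14 SE). miR167 was lower, at 28.4 ± 4.82 RPM (log2 -3.07 ± 0.36 SE, adjusted p = 4.48e-06). Root libraries 2 and 3 had less of it still (15.3 and 13.6 RPM) and root 1 more (129 RPM), and by total reads stem minus root was log2 -0.89 (adjusted p = 0.195). tasiR-ARF was lower too (log2 -1.43 ± 0.31 SE), but by total reads its adjusted p was 0.162. By the families' factors 11 families were higher and 4 lower (73.33% higher), and by total reads 13 and 1 (92.86%). With the close libraries merged 11 families were called, and 4 no longer were: miR160 (log2 -0.50 in place of -0.52, adjusted p = 0.105), miR171 (-0.65 in both, 0.0937), miR390 (0.55 in place of 0.75, 0.229) and miR858 (0.35 in place of 0.34, 0.13). miR160 and miR171 turned to 0.12 and 0.09 by total reads.

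The shoot apex, the growing tip, had little miR396: 142 ± 15.3 RPM (SD, n = 3) against 6476 ± 264 in stem (log2 -4.39 ± 0.18 SE against the mean of the other tissues, edgeR adjusted p = 9.03e-11). It was also low in miR156 (log2 -2.26 ± 0.19 SE, adjusted p = 4.28e-07) and in miR164, known to act on NAC factors of organ boundaries (5.13 ± 0.825 RPM, log2 -1.99 ± 0.25 SE, adjusted p = 1.86e-05). Higher were miR319 (690 ± 80.0 RPM, log2 1.09 ± 0.15 SE) and miR858, known to act on MYB factors (243 ± 55.4 RPM, log2 0.85 ± 0.13 SE). These 5 were called under both scalings. miR319 was lower in shoot apex than in stem (log2 -1.49, edgeR adjusted p = 3.86e-05) and was not called between flower and shoot apex (adjusted p = 0.34). miR858 did not set shoot apex apart from stem (edgeR adjusted p = 0.076) or flower (adjusted p = 0.204). miR169 was called higher as well, at only 0.810 ± 0.257 RPM. It had 0 to 3 reads per library in flower and root, so no fold is given, and with up to 2 substitutions it was no longer called (adjusted p = 0.083). By the families' factors 4 families were higher and 5 lower (44.44% higher), and by total reads 3 and 3. In place of 9, 15 families were called among those with at least 100 reads and 16 with exact matching. miR394 (log2 0.69) was no longer called without shoot apex library 3 (0.47, adjusted p = 0.275), without flower 3, leaf 3, shoot apex 2, stem 1, stem 2, root 2 or root 3 (0.65 to 0.71, adjusted p from 0.0538 to 0.0893) or with the close libraries merged (0.64, adjusted p = 0.0809), and miR168 (-0.99) was not called by total reads (adjusted p = 0.0829). miR159 turned from -0.44 to 0.37 among families with at least 100 reads and to 0.08 with exact matching.

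**Figure D3:**
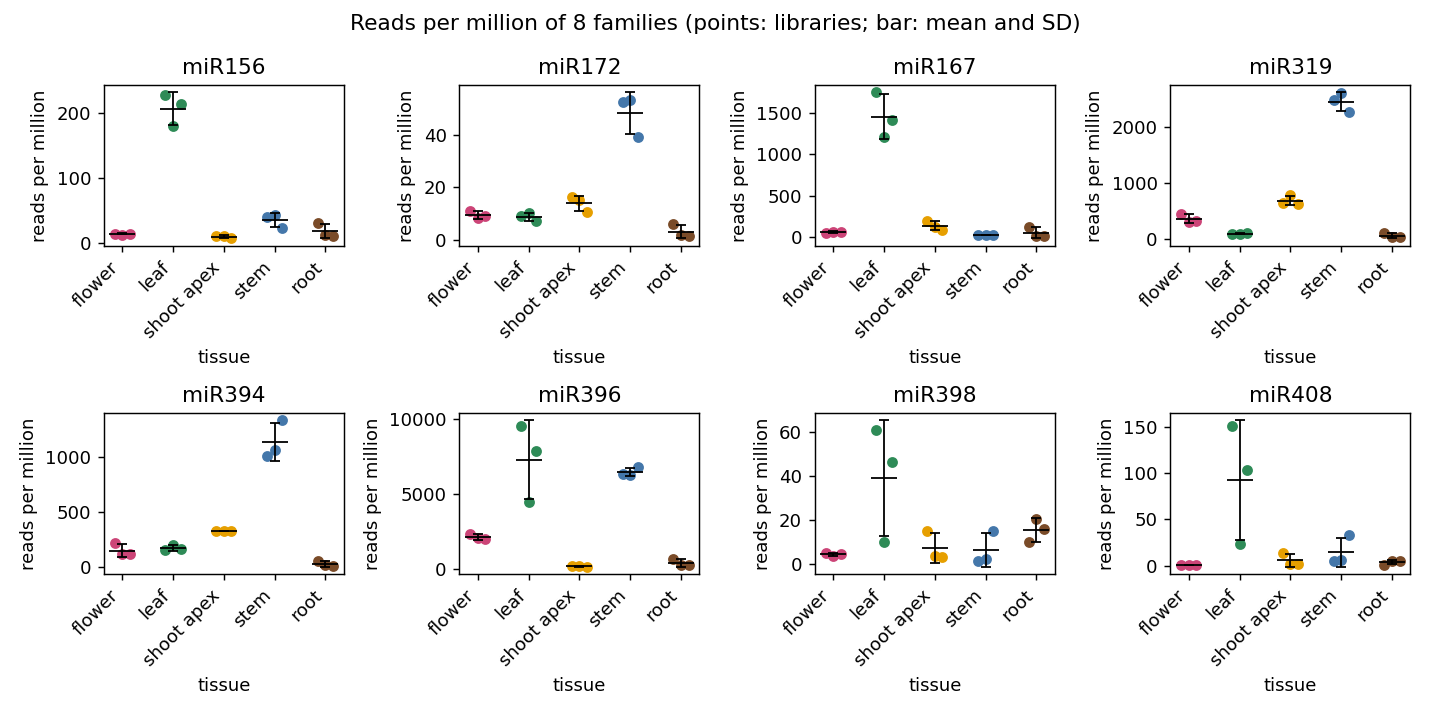
Reads per 1000000 deposited reads (vertical axes, linear) of 8 families in the 5 tissues; points are libraries, and black lines are the mean and SD of 3 libraries. miR396 averaged 142 in the shoot apex and 6476 in stem, and miR408 in leaf averaged 92.1 with an SD of 64.6.

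Flower was set apart by very low miR477, at 0.686 ± 0.303 RPM against 30.9 ± 4.53 to 111 ± 37.0 RPM in the other tissues (SD, n = 3; log2 -5.76 ± 0.39 SE, edgeR adjusted p = 4.66e-08). miR408 was also lowest in flower, at 0.864 ± 0.0886 RPM (log2 -3.41 ± 1.00 SE, adjusted p = 0.0114), although without flower library 2 it was not called (log2 -3.50, adjusted p = 0.0522). miR168 was lower as well (18.5 ± 1.17 RPM, log2 -0.94 ± 0.17 SE, adjusted p = 0.00047). These 3 falls were called under both scalings. miR168 did not set flower apart from shoot apex (flower minus shoot apex log2 0.04, edgeR adjusted p = 0.909). By RPM root had as little of miR168 (18.5 ± 7.33), while flower minus root was log2 -0.67 (edgeR adjusted p = 0.0113). miR408 was not called between flower and shoot apex (log2 -1.81, edgeR adjusted p = 0.204). Relative to the other families, miR396 (log2 1.33 ± 0.12 SE), miR160 (0.96 ± 0.18 SE), miR171 (0.81), miR319 (0.77), miR166 (0.72) and miR858 (0.45) were higher. By total reads none of the 6 was called, with miR396 at 0.74 (adjusted p = 0.0831) and miR858 at -0.14. By the families' factors 6 families were higher and 5 lower (54.55% higher), and by total reads 0 and 5. DESeq2 called 7 families.

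Root was low in miR166, miR394 and miR319 and high in miR477 relative to the other families, all called under both scalings. miR166 had 281 ± 293 RPM (SD, n = 3; log2 -2.15 ± 0.20 SE, edgeR adjusted p = 1.25e-06) and miR394 28.6 ± 25.2 RPM (log2 -2.36 ± 0.30 SE, adjusted p = 1.69e-05). miR319 had 61.6 ± 45.7 RPM (log2 -1.82 ± 0.19 SE, adjusted p = 2.26e-06). Root library 1 had the most of each. In root 1, 2 and 3, miR166 had 619, 113 and 111 RPM, miR394 57.7, 14.5 and 13.6, and miR319 114, 36.2 and 34.3. miR477 had 67.4 ± 55.1 RPM (log2 3.06 ± 0.22 SE, adjusted p = 1.23e-07), and the mean of the other tissues includes its very low flower value. It had 131 RPM in root 1, 37.5 in root 2 and 33.7 in root 3, and was not called between stem and root (edgeR adjusted p = 0.0646). miR398, known to act on copper superoxide dismutase, was higher (15.5 ± 5.38 RPM, log2 2.47 ± 0.60 SE, adjusted p = 0.00269). That call was lost by total reads (0.71, adjusted p = 0.276), and root library 1 alone gave log2 0.57. The rises of miR156 (0.48), miR164 (0.62) and miR171 (0.89) turned to -0.81, -0.86 and -0.52 by total reads. With the close libraries merged, miR156 (0.50, adjusted p = 0.0614) and miR164 (0.52, adjusted p = 0.106) were no longer called. By the families' factors 5 families were higher and 9 lower (35.71% higher), and by total reads 1 and 18 (5.26%). With the close libraries merged 11 families were called and with DESeq2 9. With root library 1 alone 8 were called, where only the other tissues give the spread. Conserved miRNA took 0.402% of the reads in root 1, 0.123% in root 2 and 0.125% in root 3. Signs of RNA quality differed in root, but did not move together between its libraries. Reads over 30 nt were 35.8% ± 1.68 in root and 12.9% to 16.4% in the other tissues. With 36.8% in root 1, 33.9% in root 2 and 36.8% in root 3, they did not follow the lower values of root 2 and 3. The median share of 20-nt among 20-nt and 21-nt family reads was 22.7% in root 2 and 20.8% in root 3, against 8.59% in root 1. The root changes were not separated from these signs.

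Between pairs of tissues 5 to 15 families differed, with 5 between flower and shoot apex and 15 between leaf and root. The order of the pairs depends on the analysis. Flower and shoot apex differed in 8 families with DESeq2 size factors, in 9 with up to 2 substitutions and in 12 with at least 100 reads, where shoot apex and stem differed in 9. Leaf and root differed in 12 with at least 100 reads, and flower and root in 15. Between flower and shoot apex, miR396 was higher in flower (log2 4.58 ± 0.19 SE, edgeR adjusted p = 1.33e-10), as was miR164 (1.87), and miR477 was lower (-4.84). miR169 was called lower in flower, from 0 to 3 reads per library there, so no fold is given. miR156 (1.25) was not called there by total reads (0.54, adjusted p = 0.341). Between leaf and stem, with 12 families called, miR167 was higher in leaf (log2 5.54 ± 0.44 SE, adjusted p = 1.59e-07), as were tasiR-ARF (2.88) and miR156 (2.42). miR319 was lower in leaf than in stem (log2 -4.75 ± 0.24 SE), as were miR394 (-2.82) and miR172 (-2.53). Between leaf and shoot apex, with 13 called, miR396 (log2 5.17), miR156 (4.00) and miR408 (3.65) were higher in leaf and miR319 (-3.26) was lower. Shoot apex and stem differed in 12 families, among them miR396 (-5.19), miR164 (-2.47) and miR168 (-1.72), lower in the apex, and miR167 (2.54). Stem and root differed in 12, with miR394 (log2 3.91), miR319 (3.82) and miR396 (2.56) higher in stem. Flower differed from leaf in 13 families, from stem in 12 and from root in 12, with miR477 lower in flower each time (log2 -4.84, -6.31 and -7.06). Leaf and root differed in 15, with miR167 higher in leaf (3.48), and shoot apex and root in 14, with miR319 higher in the apex (2.33).

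Grouped by known targets, the 7 families acting on organ growth and meristem factors (miR159, miR164, miR166, miR171, miR319, miR394, miR396) were all measured. In stem 6 were higher and 1 lower (limma fry, adjusted p = 8.53e-08, Up), and in flower 4 were higher and 1 lower (0.00047, Up). With exact matching, 3 of the stem rises turned: miR159 to log2 -0.23 (called lower, adjusted p = 0.00111), miR164 to -0.06 and miR166 to -0.07. DESeq2 did not call miR159 (0.21, adjusted p = 0.442) or miR166 (0.38, adjusted p = 0.218) in stem. By total reads none of the 4 flower rises was called, while miR159 stayed lower in flower (log2 -1.10, adjusted p = 0.0127). With exact matching miR159 was not called in flower (-0.06, adjusted p = 0.327). In root 2 were higher and 5 lower (fry adjusted p = 5.55e-05, Down), and in shoot apex 2 were higher and 3 lower (0.000157, Down). Both root rises turned by total reads (miR164 to -0.86, miR171 to -0.52), and miR171 was -3.14 in root with exact matching. miR159 turned in root with DESeq2 (0.32), at least 100 reads (0.16) and exact matching (0.08), and in shoot apex with at least 100 reads (0.37) and exact matching (0.08). miR394 in shoot apex was not called by total reads (0.93, adjusted p = 0.0622). In leaf 3 were higher and 3 lower (fry adjusted p = 0.296, Up, with a median of log2 -0.06 and a mean of -0.21). Of the 5 auxin families, 3 were higher in leaf (miR167, miR393 and tasiR-ARF; fry adjusted p = 5.46e-06, Up). In stem 3 were lower and 1 higher (0.00102, Down), in root 2 were lower (miR160 and tasiR-ARF; 0.00101, Down), in flower 1 was higher (0.0494, Up) and in shoot apex none was called (0.487). Both root calls were fragile. miR160 (log2 -0.95) was not called with DESeq2 (-0.32, adjusted p = 0.323) or with exact matching (-0.44, adjusted p = 0.0614). tasiR-ARF (log2 -0.96) was not called with DESeq2 (-0.36, adjusted p = 0.471), without root library 2 (-0.90, adjusted p = 0.0739), without library 3 (-0.68, adjusted p = 0.115) or with the close libraries merged (-0.86, adjusted p = 0.0761). The stem calls of miR160, tasiR-ARF and miR390 were fragile too. By total reads miR160 turned to 0.12 and tasiR-ARF was not called (-0.83, adjusted p = 0.162). Merging the close libraries lost miR160 (-0.50, adjusted p = 0.105) and miR390 (0.55, adjusted p = 0.229). miR390 was lost without 11 of the 15 libraries, each left out alone (0.56 to 0.75, adjusted p from 0.0528 to 0.21), and turned to log2 -2.30 with exact matching (called lower, adjusted p = 0.00031). The auxin family miR393 in leaf was no longer called without any of the 3 leaf libraries (without library 2: log2 0.72, adjusted p = 0.104). Of the phase change pair, miR156 was higher and miR172 lower in leaf (fry adjusted p = 8.35e-05, Up). They moved in opposite directions, so Up follows the larger change of miR156, and the mixed test did not pass (fry mixed adjusted p = 0.19). In shoot apex miR156 was lower (fry adjusted p = 0.000325, Down) and in stem miR172 was higher (0.000596, Up), while flower (0.256) and root (0.304) did not pass.

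The supply families for phosphate, sulfate and nitrogen (3 of 5 tested) passed in leaf, with miR395 higher (fry adjusted p = 0.0137, Up), and not in the other tissues (0.0617 to 0.885). That member (log2 1.71) was not called without leaf library 2 (0.31, adjusted p = 0.658), with the replicate block (1.498, adjusted p = 0.062), with exact matching (0.86, adjusted p = 0.196) or with at least 100 reads (1.199, adjusted p = 0.0688). Median and test of this list differed in sign in shoot apex (median log2 -1.23, mean -0.22, Up), and mean and test in flower (median 0.23, mean -0.10, Up). The copper families (miR398 and miR408 of 3) passed in leaf, with miR408 higher (fry adjusted p = 0.0136, Up), and not in the other tissues (0.101 to 0.406). The families of the small RNA machinery (miR168 and miR403 of 3) passed in leaf (fry adjusted p = 0.0214, Up), stem (0.00774, Up) and shoot apex (0.00765, Down), each with miR168 as the called member. In leaf, miR168 (log2 0.87) was not called with exact matching (0.30, adjusted p = 0.124) or with DESeq2 (0.58, adjusted p = 0.0568). In shoot apex (log2 -0.99) it was not called with at least 100 reads (-0.19, adjusted p = 0.299) or by total reads (-0.67, adjusted p = 0.0829). They did not pass in flower (0.0786) or root (0.879). Of the MYB and resistance families only miR858 could be tested (log2 0.45 in flower, -0.48 in leaf, 0.85 in shoot apex, 0.34 in stem and -1.16 in root), so this list had no set test. Adjusted over the list alone, each of the 7 lists had in each tissue the same count of called families as over all 24. By the mixed test, the organ growth list passed in all 5 tissues, leaf included (fry mixed adjusted p from 3.59e-06 to 0.000126). The auxin list passed in leaf (0.000428) and stem (0.016), and no other list passed in any tissue (0.19 or more).

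Among single sequences of 20 to 24 nt, 22013 had at least 50 reads in 3 libraries. Root had 15752 that differed from the mean of the other tissues (edgeR, adjusted p under 0.05), flower 12486, leaf 11524, shoot apex 10076 and stem 8362. Stem had 3772 with the close libraries merged, 4014 without library 1 and 3920 without library 2. Shoot apex had 5827 without library 1 and 6717 without library 2, and root had 9233 with library 1 alone, where only the other tissues give the spread. Of the called sequences of 24 nt, most were higher in shoot apex (3335 higher, 910 lower) and flower (3002 and 1300) and most were lower in root (1854 and 4233). Of the called sequences of 21 nt, most were higher in leaf (2179 and 732). Of all tested sequences the percent higher was 39.9, 35.9 and 48.9 in these 3 rises. Over all lengths, the percent of called sequences that were higher went from 49.97 by the sequences' own factors to 69.01 by total reads in leaf, from 47.7 to 75.6 in shoot apex, from 46.2 to 82.1 in stem, from 51.2 to 22.7 in root and from 51.9 to 46.2 in flower.

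The most abundant sequence higher in leaf was the 22-nt AGTTACTAATTCATGATCTGGC, with 29468 ± 10693 RPM (SD, n = 3) against a mean of 3043 RPM in the other 12 libraries (log2 3.16 ± 0.30 SE, edgeR adjusted p = 2.66e-07). The related AGTTACTAATTCATGATCTGGT had 5630 ± 1214 RPM against 494 RPM (log2 3.59 ± 0.28 SE). Neither matched a listed family or structural RNA. In stem they were the miR396 sequence TTCCACGGCTTTCTTGAACTG at 4579 ± 201 RPM (log2 2.55 ± 0.26 SE) and the miR166 sequence TCGGACCAGGCTTCATTCCCC at 1373 ± 80.9 RPM (log2 0.96 ± 0.30 SE, adjusted p = 0.0201). The latter call was lost with the close libraries merged (log2 0.92, adjusted p = 0.0828), without stem library 1 (0.92, adjusted p = 0.09) and without library 2 (1.05, adjusted p = 0.0584). Neither sequence set stem apart from leaf. Leaf libraries 1, 2 and 3 had 6709, 2808 and 5378 RPM of the miR396 sequence, and 1743, 874 and 1769 RPM of the miR166 sequence. In shoot apex the most abundant higher sequences were the 24-nt AAACGGTCTGAATCTGAACCATTC at 1271 ± 275 RPM (log2 0.68 ± 0.22 SE, adjusted p = 0.0207) and the 22-nt TCTCGTAAAGATTGTAGTTGCG at 867 ± 113 RPM (log2 2.17 ± 0.23 SE). The former call was lost without shoot apex library 2 (log2 0.73, adjusted p = 0.0562), without library 3 (0.56, adjusted p = 0.104) and with at least 20 reads (0.60, adjusted p = 0.0637). Both sequences were also abundant in flower, with ranges that overlapped those of shoot apex. Of the 24-nt sequence, flower had 1037 to 1196 RPM and shoot apex 983 to 1531. Of the 22-nt sequence, flower had 644 to 859 RPM and shoot apex 782 to 994. In flower the most abundant higher sequences were a 20-nt sequence at 3114 ± 1099 RPM matching no listed RNA and a 24-nt stretch of 5S rRNA, GCTTGGGCGAGAGTAGTACTAGGA, at 2111 ± 389 RPM against 44.5 RPM. In root they were 2 sequences of 24 nt matching no listed RNA, at 1982 ± 1344 and 1589 ± 976 RPM, with 431 and 464 RPM in root library 1. The largest rises were in rarer sequences, such as a 21-nt sequence with 74.2 ± 59.0 RPM in root and 0.163 RPM in the other 12 libraries. In flower, a 21-nt sequence had 69.3 ± 68.1 RPM against 0.0766 RPM, with 66.5% of it from flower library 3. Without a genome these could not be tied to the plant, so their bases are not given.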

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

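Signals appeared in reads that the comparisons did not use, above the 3 reads that a count of 0 allows. In the library with the most, the passenger (star) strand of miR166 had 4402 reads, that of miR396 3953, that of miR168 776, that of miR159 71 and that of miR160 25. The control family miR158 had up to 15 reads (leaf library 2). Reads over 30 nt, left out of the shares, took up to 36.81% of a library (root 3). They made up 35.8% ± 1.68 in root and from 12.9% ± 2.41 (shoot apex) to 16.4% ± 3.71 (flower) in the other tissues (SD, n = 3; exact permutation p = 0.008 between tissues).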

How the results depend on the processing

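The fits with close libraries merged and with root library 1 alone were chosen after the data were seen, all others before. All 10 shares stayed past the threshold in every alternative run. Of these, 3 changed sign: 21 nt over 20 to 24 nt reads (-1.08 points), and with distinct sequences 22 nt (-0.33) and conserved miRNA (-0.0016). Leaving out each library kept every count of families and lists within 1.5 times. The family values showed no common pairing by replicate number: 12 of 30 pairs with the same number had r over 0.1 (median -0.103, from -0.785 to 0.818). Whether libraries with the same number came from the same plant stays open. With the replicate number as a block, 11, 14, 8, 13 and 14 families were called in flower, leaf, shoot apex, stem and root, with 15 lists, and 5 named family calls were lost. Depth and spread limit small changes: 39 of 60 simulated family changes of 1 log2 unit were called.

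Family counts that moved by over 1.5 times were flower 5 (total reads), 7 (DESeq2) and 7 (at least 100 reads), shoot apex 15 (at least 100 reads) and 16 (exact matching), and root 9 (DESeq2) and 8 (root library 1 alone). Flower against shoot apex had 8 with DESeq2 size factors, 12 with at least 100 reads and 9 with up to 2 substitutions. The cause was not tested. Sequence counts in flower, leaf, shoot apex, stem and root were 6538, 6000, 5207, 4502 and 7920 with at least 100 reads, where fewer sequences were tested, and 27315, 25544, 22727, 16893 and 34374 with at least 20 reads, where more were. With fewer samples, stem had 3772 (close libraries merged) and root 9233 (library 1 alone). Leaving out 1 library gave 5827 to 12889 in shoot apex and 3920 to 12148 in stem.

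Sign changes are listed here only where a call was made in the main analysis or in the alternative, which leaves out some of the 28 of 120 above. On that count, 35 values of the named families changed direction (log2). By total reads, in line with the median shifts, they were miR858 in flower (-0.135) and leaf (0.40), miR164 in leaf (0.861) and root (-0.86), miR403 in leaf (0.889), stem (0.667) and root (-1.24), miR160 in stem (0.122), miR171 in stem (0.0917) and root (-0.52), miR156 in root (-0.81) and miR530 in root (-1.13). Leaf minus root was 0.36 for miR171 and 0.688 for miR319, and stem minus root 0.49 for miR171. With exact matching they were miR159 in shoot apex (0.0832), stem (-0.235) and root (0.0766), miR171 in shoot apex (1.45) and root (-3.14), leaf minus root (2.30) and stem minus root (2.16), and in stem miR164 (-0.0573), miR166 (-0.0662), miR390 (-2.30) and miR858 (-0.425). With at least 100 reads they were miR159 in shoot apex (0.369) and root (0.162), miR171 in shoot apex (0.70), miR858 in stem (-0.125) and miR168 in root (0.40). In root, DESeq2 size factors gave miR159 0.32 and miR168 0.57, the DESeq2 test miR159 0.316, and root library 1 alone miR164 -0.0569. Exact matching left out the leading miR396 sequence, which had 1 substitution against the listed core. It thus changed the family reads from which the factors come. In root the second member of miR171 took 97.8% of the reads of both leading members. The sign changes were not traced to single sequences, and their cause was not tested. Otherwise, 119 values of named families lost and 65 gained a call, and leaving out libraries ended 77 calls and added 23.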

Other observations

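Fragments of structural RNA differed by tissue. Fragments of 5S rRNA had 16060 ± 1855 reads per 1000000 reads of 18 to 30 nt in flower (SD, n = 3), 6.25 times the mean of the other 12 libraries and above all of them in 3 of 3. The p-values of this paragraph are exact permutation tests between the 5 tissues, adjusted over 14 RNAs, and not of 1 tissue against the others (5S rRNA: exact permutation p = 0.00011, adjusted p = 0.00052). In leaf, plastid fragments of initiator methionine tRNA (491 ± 140, 8.31 times the others), glycine tRNA (1483 ± 81.9, 6.88 times) and 16S rRNA (1840 ± 46.8, 5.06 times) lay above all other 12 libraries in 3 of 3 (exact permutation between tissues, adjusted p = 0.00037, 0.0044 and 0.001). Nuclear fragments of glutamate tRNA had 1005 ± 582 in root, 3.52 times the others and above all of them in 2 of 3 libraries (exact permutation between tissues, adjusted p = 0.036). The miR166 star strand had 146 ± 24.4 RPM in flower, 142 ± 46.5 in stem and 64.3 ± 10.01 in leaf, where miR166 itself had 1699 ± 163, 3371 ± 288 and 3696 ± 847 (SD, n = 3; the star strands were not tested).

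The tests of mixed tissue and of a wrong label were set before their results were seen, and all others here, those on other splits included, after. Of 6 relations among miR395, miR398, miR399 and miR408 between libraries of the same tissue, with tissue means removed, 5 passed. These families had the largest SD within tissues of those tested (log2 1.24, 1.17, 1.08 and 1.32). The adjustment over 6 relations does not cover their choice among 24 families. The closest was between miR398 and miR408 (r = 0.943 over 15 libraries, exact permutation p = 0.00129, adjusted p = 0.00772 over 6 relations; rho = 0.914, exact p = 0.00296; r = 0.928 without the 2 farthest libraries). miR399 rose with miR398 (r = 0.833, exact permutation p = 0.0243, adjusted p = 0.0365; rho = 0.850, exact p = 0.0193; r = 0.728 without the 2 farthest) and with miR408 (r = 0.717, exact permutation p = 0.0341, adjusted p = 0.0409; rho = 0.664, exact p = 0.0423; r = 0.489 without the 2 farthest). miR395 fell as miR398 rose (r = -0.555, exact permutation p = 0.0072, adjusted p = 0.0144; rho = -0.657, exact p = 0.0201; r = -0.662 without the 2 farthest) and as miR408 rose (r = -0.712, exact permutation p = 0.0045, adjusted p = 0.0135; rho = -0.814, exact p = 0.0045; r = -0.729 without the 2 farthest). miR395 and miR399 did not pass (r = -0.158, exact permutation p = 0.581, adjusted p = 0.581; rho = -0.343, exact p = 0.278; r = -0.534 without the 2 farthest). For miR398 and miR408 the tables argue against counting noise, since the variance within tissues was at least 38.5 times the counting variance. The median SD of the other families was 0.472 of theirs. That ratio cannot decide on a shift of the whole library, since families with the largest SD were compared with the rest. With scaling by the families' factors r between miR398 and miR408 was 0.954, so a shift shared by the families does not account for the relation. A mixture of tissues stays open: r between the plastid share and miR408 was 0.415 (exact permutation p = 0.175; rho = 0.404, exact p = 0.241; r = 0.188 without the 2 farthest). No biological explanation was tested.

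Root libraries 2 and 3 held fewer 24-nt reads and more structural RNA than root library 1. RNA breakdown may contribute: the share of 20-nt among 20-nt and 21-nt family reads was higher by a median of 16.22 percentage points over 13 families, and higher in 10 of them. Size selection is argued against, since the 24-nt share was 0.513 times that of root 1, below 23 nt (0.791) and 25 nt (1.453). A wrong label is argued against too: the highest rank correlation with another tissue's library was 0.498, against 0.818 and 0.817 with root library 1. A difference between the sampled roots themselves stays open, as untested.

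Members of a family took different shares in different tissues. The miR171 sequence TGATTGAGTCGTGCCAATATC, which differs from TGATTGAGCCGTGCCAATATC by C9T (counted from 1 at the 5′ end), took 97.8% ± 1.67 of the reads of both in root, and from 8.77% ± 4.17 (leaf) to 39.9% ± 2.95 (stem) in the other tissues (SD, n = 3; exact permutation p = 4.3e-06, adjusted p = 5.1e-05 over 12 families). The second member of miR164 (T14C) took 17.6% ± 11.5 in shoot apex and 67.2% ± 3.51 in leaf, and that of miR396 (G7A) 2.98% ± 0.735 in root and 18.7% ± 6.23 in shoot apex (SD, n = 3; exact permutation, adjusted p = 0.0018 and 0.00053). Sequencing error in the leading member is argued against for these 3 of 12 families, whose shares differed between tissues by over 10 points. Different loci are a candidate explanation that was not tested, as no genome was at hand.

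Other splits of the 15 libraries were counted. Of 100 splits, 1, the real one, called as many families that differed between tissues (18, highest other 4), and the same held in flower (11 and 5), leaf (15 and 6), shoot apex (9 and 6), stem (15 and 4) and root (14 and 6) and for the lists (16 and 3). Of 60 splits, 1, the real one, called as many single sequences in flower (12486, highest other 11263), leaf (11524 and 2233), shoot apex (10076 and 242), stem (8362 and 2505) and root (15752 and 1973). At 1 of 100 and 1 of 60, the smallest shares possible, an arbitrary grouping of these libraries is unlikely to give such counts. Splits that mix tissues raise the spread within groups, so they cannot gauge chance differences between plants. The split with 11263 in flower put the 3 root libraries in the place of flower. For pairs of tissues the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, called as many each time. The real and highest other counts were 13 and 1 for flower and leaf, 5 and 1 for flower and shoot apex, 12 and 0 for flower and stem, 12 and 0 for flower and root, and 13 and 0 for leaf and shoot apex. They were 12 and 4 for leaf and stem, 15 and 1 for leaf and root, 12 and 0 for shoot apex and stem, 14 and 1 for shoot apex and root, and 12 and 3 for stem and root.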
